A study of Homo sapiens with 12 samples.

How the data were processed

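RNA of the ALDH-positive fraction of 697 (EU3) cells, a human B-cell precursor leukaemia line, was measured in 12 libraries. ALDH-positive cells carry high aldehyde dehydrogenase activity, which a fluorescent substrate reveals for sorting. Per the labels, SH2 is a doxycycline-inducible shRNA against IGF2BP1 with a green fluorescent reporter, and treated SH2 cells were sorted for the reporter after doxycycline. The labels call the remaining libraries the control for doxycycline treatment and do not say whether they carry the scrambled shRNA that the protocol mentions. Libraries were made per the labels with a QuantSeq kit that captures the end of each transcript next to the poly(A) tail, so a gene is counted mainly at its last exon. The design text gives 4 sets, each from its own sort and its own doxycycline treatment. SH2 cells were present untreated and treated in sets 1 to 4 (n = 4 per group), and control cells untreated and treated in sets 2 and 4 (n = 2 per group).

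The deposited counts are whole reads per gene from HTSeq, per the submitters' processing notes, which also name FastQC, STAR, DESeq2 and the build hg38 (GRCh38). Versions and the annotation are not given in the sources used here. Each count table held 64253 gene IDs and 5 HTSeq summary lines, which were kept out of library sizes and tests. Of all reads in the tables, alignments that were not unique took 42.2% to 63.8% per library, reads outside genes 3.25% to 7.73% and ambiguous reads 1.11% to 1.62%. The authors also deposited a table of normalized signal for 26231 genes, each column of which equalled the counts times a constant of that library. All of its values came out whole after division by that constant (100%, tolerance 0.01), and equalled the counts; the count test on these recovered reads called 2 genes in treated against untreated SH2 cells. All columns of that table belonged to a library used here. Gene names came from this table, and every one of the 11968 genes tested had one. Positions are from GENCODE v29 on GRCh38.

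Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept with filterByExpr by group (minimum count 10), libraries scaled by TMM, and all 12 libraries fitted at once with 1 term per group by the robust quasi-likelihood method. The contrasts tested were these: treated against untreated SH2 cells, treated against untreated control cells, the difference between these responses (the interaction), and SH2 against control cells without and with doxycycline. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 0.376. Levels are CPM with TMM-scaled library sizes. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts it is a ratio with an exact 95% interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Before the data were examined, 38 gene lists holding 761 genes were fixed, of which 760 were found; 36 lists had at least 3 tested members. Lists were tested on log2 CPM (prior count 3) with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the 36 lists. The genes named were those past the threshold with a mean log2 CPM of at least 3 that moved alike in every set, or whose groups did not overlap, up to 10 per direction by fold, leaving out clone names and other symbols that are no gene name; the 5 smallest p-values where fewer than 5 genes passed; the genes of the series title and their family; and the 4 members of each list with the smallest p-values. RP11-864N7.2, CD3D, SLC16A3, TPI1, the value of MSMO1 in untreated cells and the second gene ID of HLA-DQA1 fall outside this rule and were chosen after their values were seen. A gene that this rule names and a gene list are not reported here.

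Replicates were separate sorts and treatments per the design text. No replicate pair agreed within sampling noise: the chi-square per degree of freedom ran from 9.29 to 54.5. Set numbers come from the labels. Deviations from the group means correlated between same-set untreated and treated SH2 libraries at 0.188 to 0.663 and between libraries of other sets at -0.548 to 0.272, and all 4 pairs passed the minimum of 0.1, so the numbers were taken to pair the samples. Of the treated SH2 libraries 3 of 4, and of the untreated 4 of 4, were best matched by their own set. The main fit had no term for the set. Alternatives were DESeq2 size factors, no filter on low counts, the set as a block, the Wald test of DESeq2 1.42.0, a fit on the compared groups alone, limma-trend on the deposited table (pseudocount 1), and leaving out each library. The tests on simulated data were made after the first fit of the real data. In simulated counts with 200 changed genes, the test of treated against untreated SH2 cells recovered 56.1% of 66 genes changed 4-fold and 2.99% of 67 changed 2-fold over 11556 genes, with 2 other genes called. For treated against untreated control cells it recovered 15.2% at 4-fold over 11568 genes, and for the interaction 1.52% over 11562 genes. For SH2 against control cells it recovered 19.7% at 4-fold without doxycycline over 11573 genes and 19.7% with it over 11581 genes. In simulated lists of 29 genes over 11968 genes, camera called 5 of 5 lists shifted by -0.4 in treated against untreated SH2 cells, 3 of 5 in control cells, 2 of 5 in the interaction, and 4 and 5 of 5 in SH2 against control cells without and with doxycycline, and 0 of the other lists. The simulated genes were drawn independently. Real list members moved together (estimated correlation 0.131 for MYC targets and 0.439 for interferon genes), so false calls in such lists are not covered. The search for short sequence words in the closing section was tested on simulated shifts of -0.15 over 10614 genes: the planted word was lowest in 20 of 20 draws, and with nothing planted a word passed the correction in 2 of 20. Fold changes were shuffled over genes there, which removes shared movement as well. An explanation of the control libraries as a mixture of cells was dropped without a test.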

Results

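The series asks what an shRNA against IGF2BP1, an RNA-binding protein of fetal tissues and tumours, changes in ALDH-positive 697 leukaemia cells, and its title names HOXB4, MYB and ALDH1A1 as genes regulated by it. Between 2210291 and 3370952 reads were assigned to genes per library, and 15847 to 17439 genes had a count. On the first principal component (47.0% of the variance) SH2 and control libraries lay apart, and on the second (17.6%) the treated SH2 library of set 4 lay at -76.1, beyond all others. That library correlated with the other SH2 libraries at 0.832 to 0.908, against a median of 0.926 between libraries of the same cells from different sets.

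**Figure D1:**
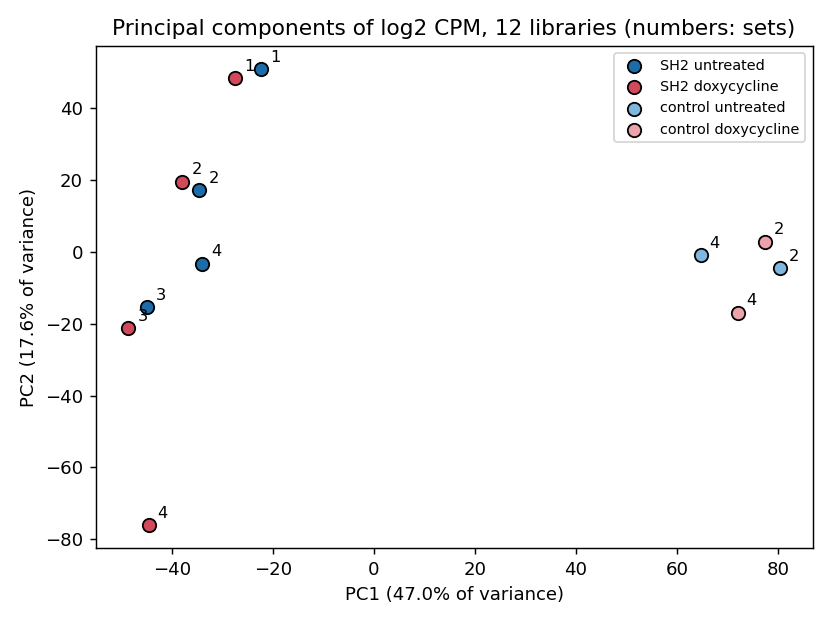
Principal components of log2 CPM for the 12 libraries, with PC1 on the x axis, PC2 on the y axis and the set number beside each point. SH2 libraries lie at negative PC1 and control libraries at positive PC1, and the treated SH2 library of set 4 lies at -76.1 on PC2.

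IGF2BP1 (ENSG00000159217, chromosome 17, 48997412 to 49055650) was lower in treated than untreated SH2 cells in 4 of 4 sets. Its level was 21.7 against 6.28 CPM in set 1, 30.5 against 14.8 in set 2, 39.2 against 25.0 in set 3 and 32.9 against 16.2 in set 4. The group means were 31.1 ± 7.23 and 15.6 ± 7.68 CPM (SD, n = 4 each), a log2 fold change of -0.99 ± 0.43 (SE), or 1.99-fold lower. The change had an unadjusted edgeR p of 0.0371, and it did not pass over all genes (adjusted p = 0.983) or adjusted over the list alone with the other title genes (0.0743). In control cells IGF2BP1 was close to the limit of detection: 1.42 and 0 CPM without doxycycline and 0.961 and 0.382 with it, in sets 2 and 4, from 3 and 4 counts in all. Reads were counted at the transcript's end, so these values follow the IGF2BP1 mRNA and not its protein.

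The other title genes had low counts or moved differently between sets. HOXB4 (ENSG00000182742, chromosome 17, 48575513 to 48580111), a homeobox factor of blood stem cells, had 11 counts over the untreated and 1 over the treated SH2 libraries, a ratio of 9.93 (95% counting interval 1.44 to 427). Its edgeR adjusted p was 0.983 over all genes and 0.033 adjusted over the list alone. MYB (ENSG00000118513, chromosome 6, 135181315 to 135219173), a transcription factor of blood progenitors, had a log2 fold change of -0.53 ± 0.41 (SE, adjusted p = 0.983), with set values of -0.93, 0.13, 0.81 and -1.90. ALDH1A1 (ENSG00000165092, chromosome 9, 72900662 to 73080442), which encodes an aldehyde dehydrogenase, had -0.67 ± 0.80 (adjusted p = 0.986), with set values of -0.56, -0.67, 0.20 and -1.05 and untreated levels of 22.1, 16.3, 1.30 and 3.92 CPM in sets 1 to 4. Without single libraries ALDH1A1 ran from -1.35 (treated set 1) to -0.09 (untreated set 1), and it was -1.04 and -0.39 without untreated sets 3 and 2, -0.34 and -0.32 without treated sets 3 and 4. MYB became -0.09 without untreated set 1 and -0.27 without treated set 4, and HOXB4 -4.42 without treated set 4. As a list the 4 title genes were lower (camera adjusted p = 0.0163, adjusted p = 0.31 with an estimated correlation). The title of this same series names them, so the list cannot be taken as independent evidence of its direction. The call was lost without the untreated SH2 library of set 1 (adjusted p = 0.0664) or the treated one of set 4 (0.0918). IGF2BP3, a paralogue, had -0.24 ± 0.26 (adjusted p = 0.986; -0.05 and -0.15 without the untreated and treated SH2 library of set 4, 0.03 without both), and IGF2BP2 had 2 counts, both in treated control cells of set 2.

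RPS12 fell with doxycycline in SH2 cells, as did the reads counted for its processed pseudogene RP11-864N7.2. No other gene of 11968 passed the threshold in the edgeR fit. RPS12 (ENSG00000112306, chromosome 6, 132814441 to 132817564), a protein of the small ribosomal subunit, went from 8833 ± 1244 to 1408 ± 549 CPM (SD, n = 4 each), a log2 fold change of -2.65 ± 0.35 (SE, adjusted p = 0.0211). The set values were -2.78, -2.26, -2.29 and -3.71. In control cells RPS12 stood at 8452 ± 2510 CPM untreated and 10150 ± 3710 treated (SD, n = 2 each). RP11-864N7.2 (ENSG00000227615, chromosome 11, 74745716 to 74746114) had -3.25 ± 0.44 (adjusted p = 0.0211) on 151 against 14 counts. It is a near-identical copy of RPS12, so its reads cannot be assigned to it with certainty. Per library it had 26 to 50 counts beside 25904 to 28412 of RPS12 in untreated SH2 cells. In treated SH2 cells it had 2 to 5 beside 1772 to 5252, and in control cells 22 to 45 beside 18470 to 39853. Stray RPS12 reads could give such counts, so both calls may be the same signal. The remaining genes with the smallest p-values had adjusted p = 0.0796: RAB1B, a GTPase of transport from the endoplasmic reticulum, at -1.39 ± 0.23; EXOSC5, a subunit of the RNA exosome, at -1.59 ± 0.26; and KARS, the lysyl-tRNA synthetase, at -1.21 ± 0.21. Each was lower in 4 of 4 sets. With the set as a block 6 genes passed, 0 higher and 6 lower: RPS12 (adjusted p = 0.00034), RP11-864N7.2 (0.00874), RAB1B (0.0243), EXOSC5 (0.0243), KARS (0.0371) and SRM, the spermidine synthase (-1.55, 0.0243). Without a filter on low counts 47 genes passed, among them RAB1B (adjusted p = 0.019), EXOSC5 (0.00146), KARS (0.0257) and SRM (0.00138). At an unadjusted p under 0.05 there were 584 genes, and DESeq2 called 16 (2 higher, 14 lower). In a fit on the SH2 libraries alone 0 genes passed (RPS12 adjusted p = 0.0937). RPS12 also missed the threshold without the untreated library of set 1 (adjusted p = 0.0851) or 4 (0.0859) or the treated library of set 2 (0.128) or 3 (0.126). Its log2 fold changes there were -2.55, -2.70, -2.77 and -2.77. RP11-864N7.2 missed it without these and without the treated library of set 4 (0.0862). EXOSC5 passed without the treated library of set 1 (0.0321).

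**Figure D2:**
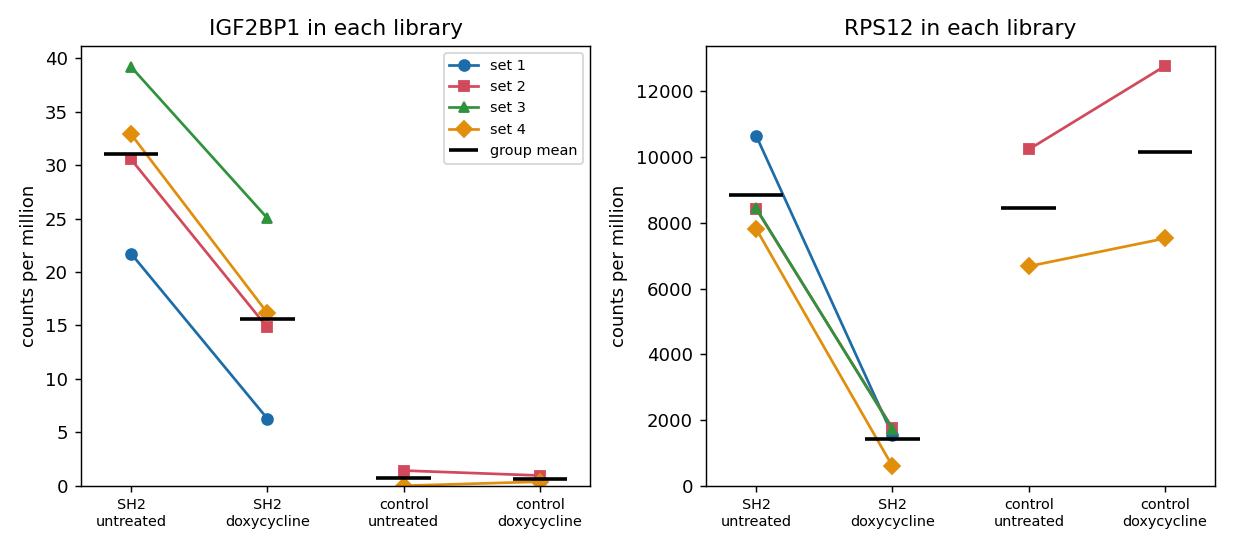
CPM of IGF2BP1 and RPS12 in each library, with lines joining the untreated and treated library of a set and black bars at group means. In SH2 cells both are lower with doxycycline in 4 of 4 sets, and in control cells IGF2BP1 stays at or under 1.42 CPM.

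Targets of MYC, mainly nucleolar and ribosome assembly genes, fell as a list in treated SH2 cells. Of 29 tested members 3 had a positive and the others a negative log2 fold change, with a median of -0.48 (camera adjusted p = 3.52e-10, adjusted p = 0.262 with an estimated correlation). No member passed over all genes and 1 was lower adjusted over the list alone. The smallest p-values were those of SRM (-1.48 ± 0.36), the ribosome assembly factor BOP1 (-0.88 ± 0.25), the helicase DDX18 (-0.96 ± 0.30) and nucleolin NCL (-0.80 ± 0.26). The medians within sets were -0.485, -0.301, -0.227 and -0.71, while in control cells they were -0.303 in set 2 and 0.135 in set 4. Genes of the unfolded protein response (median -0.34, 17 of 18 negative, adjusted p = 0.00134; 0.749 as adjusted p with an estimated correlation) fell too. Their members included the chaperone genes DNAJC3 (-1.42 ± 0.39; past the threshold without a filter on low counts, adjusted p = 0.00385) and DNAJB11 (-0.98 ± 0.32; -0.64 without untreated set 4), and the call was lost without the treated library of set 1 (adjusted p = 0.124) or the untreated one of set 4 (0.522). Smaller shifts downward were called for fatty acid synthesis (11 of 11 negative, median -0.33, adjusted p = 0.00907, adjusted p = 0.749 with an estimated correlation) and MHC class II genes (5 of 5 negative, -0.32, adjusted p = 0.0163, adjusted p = 0.749 with an estimated correlation). They were also called for ATF4 targets of the integrated stress response (29 tested, -0.24, adjusted p = 0.0184, adjusted p = 0.837 with an estimated correlation) and translation factors (24 tested, -0.13, adjusted p = 0.0241, adjusted p = 0.705 with an estimated correlation). Adjusted over the list alone, 1 MHC class II gene and 1 translation factor were lower, and 0 members of the other lists. Over all genes, HLA-DQA1 of MHC class II passed without a filter on low counts (-1.66, adjusted p = 0.0171). The translation factor EIF4G2 passed with the Wald test of DESeq2 (-1.05, adjusted p = 0.00264). Each of these list calls was lost without single libraries. Fatty acid synthesis was lost without untreated set 2 (adjusted p = 0.0546) or treated set 4 (0.481), and MHC class II genes without untreated set 1 (0.0726) or 2 (0.15) or treated set 3 (0.113) or 4 (0.0902). ATF4 targets were lost without treated set 1 (0.763) or untreated set 2 (0.15), 3 (0.145) or 4 (0.179), and translation factors without untreated set 2 (0.0546) or 4 (0.179) or treated set 1 (0.0566), 3 (0.0569) or 4 (0.0887). In all, camera called 9 of 36 lists, with an estimated correlation 0 and with fry 0. The estimated correlation and fry were used without a term for the set, so differences between sets remain in the spread they rest on. Neither was repeated with the set as a block.

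Interferon-response genes rose as a list in treated SH2 cells, with 23 of 25 members positive and a median log2 fold change of 0.70 (camera adjusted p = 0.000646, adjusted p = 0.749 with an estimated correlation). The members with the smallest p-values were IFI44L, IFI6 and MX1, which are switched on by interferon, and none passed over all genes or adjusted over the list alone. Without a filter on low counts all 3 passed over all genes: IFI44L (log2 6.00, adjusted p = 1.98e-15), IFI6 (2.41; 2.91e-07) and MX1 (2.24; 8.36e-06). The shift was mostly that of the treated library of set 4, which stood apart from the other SH2 libraries: the median was 1.16 there and 0.115, 0.274 and -0.077 in sets 1 to 3. Without that library the list did not pass (adjusted p = 0.838), and without both SH2 libraries of set 4 it did not pass (0.242). Without that library the log2 fold change of IFI44L went from 6.04 to 1.44 (adjusted p = 0.991), that of IFI6 from 2.45 to 0.51 (0.991) and that of MX1, at 161 CPM there, from 2.29 to -0.22 (0.999), in the filtered fit. Mitochondrially encoded transcripts rose as well, with 11 of 15 positive and a median of 0.32 (adjusted p = 0.00134, adjusted p = 0.749 with an estimated correlation). MT-CO1, a subunit of cytochrome oxidase, had 1.45 ± 0.39 (0.82 without the treated library of set 4; adjusted p = 0.00427 without a filter on low counts) and MT-ND5, a subunit of complex I, 1.13 ± 0.35, and 2 members were higher adjusted over the list alone. The call was lost without the untreated library of set 2 (adjusted p = 0.187). In control cells the medians of this list were 0.31 in set 2 and -0.038 in set 4. The interaction was not called for it (camera adjusted p = 0.148), so a rise particular to SH2 cells is not shown.

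**Figure D3:**
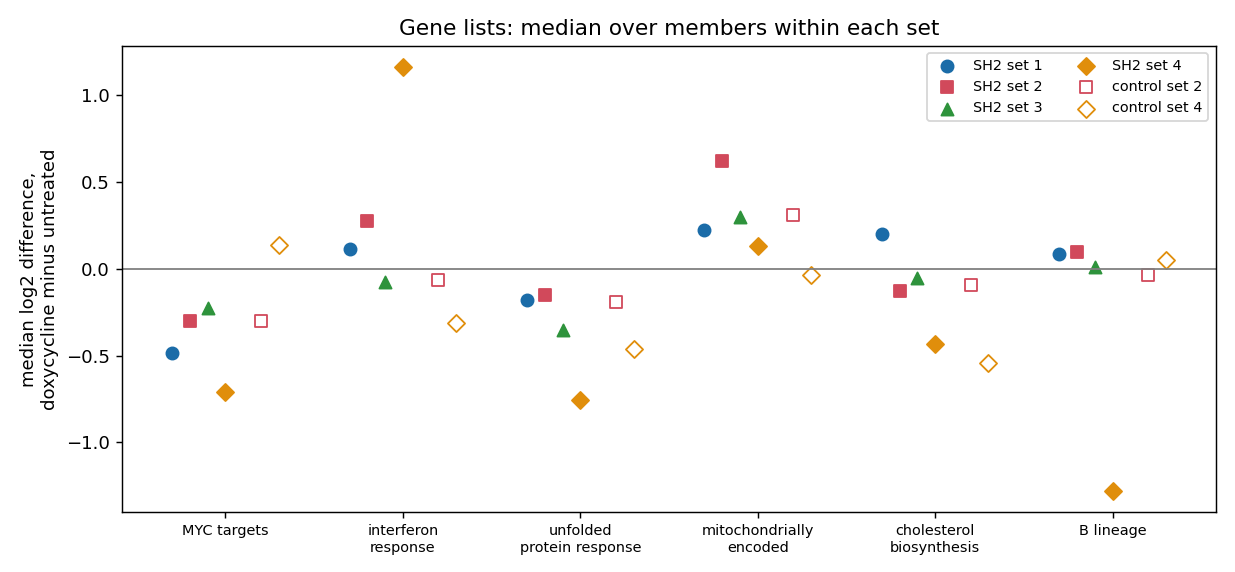
Median log2 difference between the treated and untreated library of each set over the members of 6 gene lists, with filled symbols for SH2 and open symbols for control cells. MYC targets are below 0 in all 4 SH2 sets, whereas the interferon median is 1.16 in set 4 and between -0.077 and 0.274 in the other SH2 sets.

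Cholesterol synthesis genes fell as a list with doxycycline in control cells, which differed from SH2 cells in their light chain. Of 23 members 2 were positive, with a median log2 fold change of -0.41 (camera adjusted p = 3.02e-07, adjusted p = 0.312 with an estimated correlation). Among them were MSMO1 (-0.90 ± 0.43) and IDI1 (-0.76 ± 0.38), enzymes of the sterol and isoprenoid steps. The unfolded protein response list was also lower, at a median of -0.35 (adjusted p = 0.0273, adjusted p = 0.977 with an estimated correlation). The cholesterol call was lost without the treated library of set 4 (adjusted p = 0.164), and that of the unfolded protein response without the treated library of set 2 (0.848) or the untreated one of set 4 (0.569, in the opposite direction). By edgeR 0 genes passed and 82 had an unadjusted p under 0.05, while DESeq2 called 0 and edgeR without a filter on low counts 3, DHRS2 (adjusted p = 0.000109) among them. The smallest p-values belonged to DHRS2 (104 counts untreated against 2 treated; ratio 61.2, 16.5 to 512), GABRD and IGLL5 (16 against 1 count each), PLXNC1 (-1.59 ± 0.52) and EPG5 (-1.30 ± 0.43), all lower with doxycycline and with an adjusted p of 1. DHRS2 stood at 36.9 and 0.949 CPM in the untreated libraries. Without the untreated library of set 4 DHRS2 went from -5.61 to -1.33 and PLXNC1 to -0.90, and without the treated one of set 2 GABRD went from -3.94 to -6.22 and IGLL5 from -3.88 to -6.16. With 2 libraries per group, 15.2% of genes changed 4-fold in simulated counts were recovered.

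In the test of whether SH2 and control cells responded differently to doxycycline, camera called 3 lists, but 0 with an estimated correlation and 0 with fry. By edgeR 0 genes passed, with 116 at an unadjusted p under 0.05. RPS12 had the interaction -2.91 ± 0.58 (adjusted p = 1), which passed with the set as a block (-2.99, adjusted p = 0.0451), with DESeq2 (0.00667), which called 2 genes, and without a filter on low counts, where 3 passed. MYC targets were lower in SH2 than in control cells in this contrast (median -0.33, 27 of 29 negative; camera adjusted p = 3.84e-06, adjusted p = 0.456 with an estimated correlation). Interferon genes were higher (median 1.05, 24 of 25 positive; 3.84e-06, adjusted p = 0.961 with an estimated correlation), and the call was lost without the treated SH2 library of set 4 (adjusted p = 0.0803) but not without both SH2 libraries of that set (0.00896). Cholesterol synthesis genes were higher (median 0.36, 18 of 23 positive, adjusted p = 0.00468, adjusted p = 0.796 with an estimated correlation), and lost the call without the untreated (0.0583) or treated (0.587) control library of set 4. Their medians in SH2 and control cells lay close within set 2 (-0.13 and -0.093) and within set 4 (-0.436 and -0.544). SH2 sets 1 and 3, which have no control libraries, had 0.198 and -0.054. Across 11968 genes, which are not independent replicates, the log2 fold changes of both responses had a Pearson r of 0.168 and a Spearman rho of 0.192. Pearson r was 0.009 without the untreated control library of set 4, 0.075 without the treated control library of set 2, 0.077 without the untreated SH2 library of set 4 and 0.089 without both SH2 libraries of set 4.

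SH2 and control cells differed widely before doxycycline, starting with the immunoglobulin light chain. SH2 cells expressed lambda constant genes and control cells the kappa gene: IGKC (chromosome 2, 88857161 to 88857683) took 99.7% to 100% of light chain counts in control libraries and at most 0.154% in SH2 libraries. IGLC7 (chromosome 22, 22922594 to 22923034) had 3852 counts against 0, at least 512-fold higher in SH2 cells, and the IGLC genes are near-identical copies whose reads may be split. IGF2BP1 was higher in SH2 than in control cells (386 against 3 counts; ratio 51.3, 17.4 to 250, adjusted p = 0.000915), and HOXB4 was lower (-4.62 ± 0.57, adjusted p = 0.000185). In all 938 genes differed, 352 higher and 586 lower in SH2 cells, and with the set as a block 1505 (687 higher, 818 lower). Without the untreated control library of set 2 the count was 343 and without that of set 4 it was 490.

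**Figure D4:**
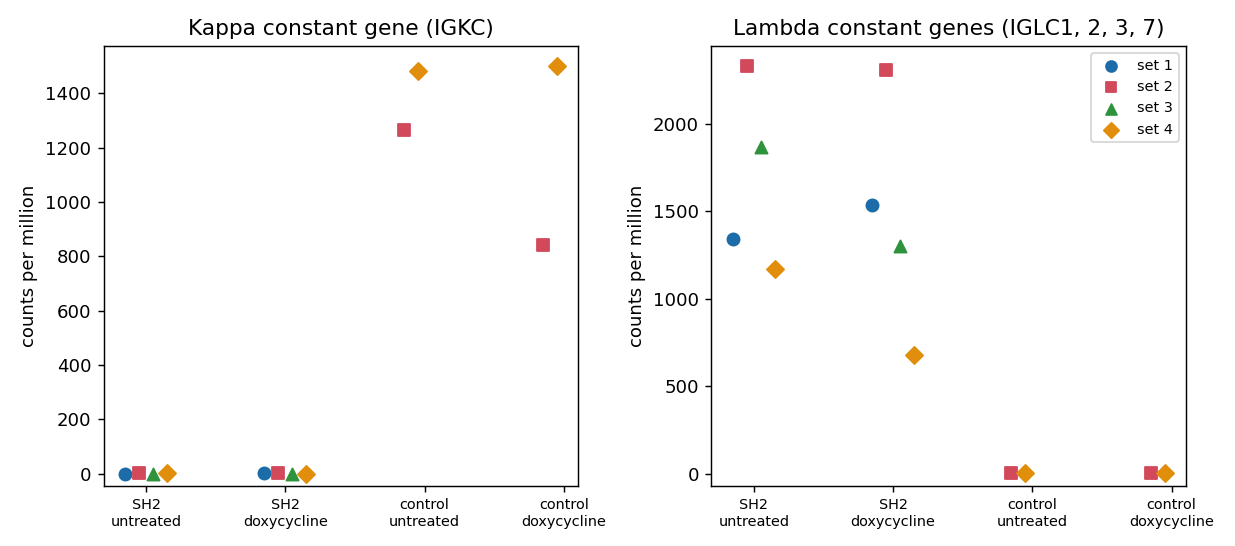
CPM of the kappa constant gene and of the lambda constant genes summed in each library, coloured by set. Control libraries hold kappa and SH2 libraries lambda counts, with at most 0.154% kappa in any SH2 library.

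Among the genes absent from control libraries at this depth were the ion channel TRPM4 (at least 94.2-fold higher in SH2 cells), the taste receptor TAS1R1 (at least 91.9-fold), the glutathione transferases MGST2 (at least 79.5-fold) and MGST1 (at least 47.9-fold). Others were the synaptic gene RIMS4 (at least 72.5-fold), the transcription factor FOXC1 (at least 57.9-fold), GTSF1 (at least 47.4-fold) and the adhesion molecule CADM1 (at least 47.0-fold). IGLC2 was higher too (log2 9.61 ± 1.61). Absent from untreated SH2 libraries were the decoy receptor IL1R2 (at least 936-fold lower), ITM2A (at least 538-fold), and the cytokine subunit EBI3 (at least 413-fold). So were FCRL3 (at least 238-fold lower), NLRP4 (at least 190-fold), DTX3 (at least 185-fold) and FAM129A (at least 173-fold). The chemokine CCL22 had 712 counts in control against 1 in SH2 cells (ratio 1784, 319 to 70580) and CR2, the complement receptor of mature B cells, 769 against 2 (ratio 964, 266 to 7971).

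Genes of antigen presentation were lower in SH2 cells. Of 5 tested MHC class II genes 4 were lower, over all genes and adjusted over the list alone. They included HLA-DQA1 (-5.42 ± 0.53) and its activator CIITA (-3.19 ± 0.33), with a list median of -2.67 (camera adjusted p = 1.71e-05, adjusted p = 0.386 with an estimated correlation). HLA genes share sequence and some have a second gene ID, so their counts are uncertain: under its other ID HLA-DQA1 had -9.15 ± 0.63. The B lineage list was not called (median -0.18, 13 of 31 positive, camera adjusted p = 0.132), and of its 31 genes 7 were lower and 0 higher (9 lower and 2 higher adjusted over the list alone), among them the transcription factor SPIB (-6.16 ± 0.57) and MS4A1, which encodes CD20 (-7.66 ± 1.01). Targets of NF-kB were lower in SH2 cells as well, 5 of 13 passing (6 adjusted over the list alone), with BCL2A1 at -6.73 ± 0.60 and BIRC3 at -4.05 ± 0.55 and a median of -0.75 (adjusted p = 9.84e-05, adjusted p = 0.22 with an estimated correlation). The other called lists were nuclear oxidative phosphorylation genes (median -0.34, adjusted p = 0.783 with an estimated correlation), glycolysis (-0.71, adjusted p = 0.783 with an estimated correlation), and cholesterol synthesis (-0.48, adjusted p = 0.783 with an estimated correlation). Called higher were ATF4 targets (0.47, adjusted p = 0.783 with an estimated correlation), the unfolded protein response (0.75, adjusted p = 0.783 with an estimated correlation) and 4 myeloid genes including CD33, of which 4 were higher by fitted value, 1 passed and 3 passed adjusted over the list alone (adjusted p = 0.386 with an estimated correlation). Over all genes 1 of 44 oxidative phosphorylation genes was lower and 0 higher, also adjusted over the list alone. Of 21 glycolysis genes 1 was lower and 1 higher over all genes, and 3 lower and 1 higher adjusted over the list alone. The higher one was SLC16A3, a lactate transporter (4.18 ± 0.94), and the lower one over all genes TPI1, the triosephosphate isomerase (-1.41 ± 0.33), both chosen after their values were seen. Of 23 cholesterol synthesis genes 4 were lower and 0 higher over all genes, and 7 lower and 1 higher, MSMO1 (1.13 ± 0.38), adjusted over the list alone. No ATF4 target and no gene of the unfolded protein response passed either way. Without the untreated control library of set 2 the calls of oxidative phosphorylation (adjusted p = 0.0879), glycolysis (0.759), ATF4 targets (0.342), the unfolded protein response (0.499) and myeloid genes (0.0663) were lost. Leaving out single untreated SH2 libraries ended those of glycolysis (0.0567 without set 1, 0.0592 without set 3), ATF4 targets (0.0522 without set 2, 0.0526 without set 4) and the unfolded protein response (0.199 without set 4). The list of T and NK cell genes was not called (9 tested, 2 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.143). CD3D, a T-cell receptor component chosen after its values were seen, reached 232 and 241 CPM in the untreated and treated libraries of control set 2, against 10.5 and 8.79 in control set 4 and 2.87 to 18.7 over the SH2 libraries.

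The difference between the cells was much the same with doxycycline, where 1326 genes passed, 550 higher and 776 lower in SH2 cells, and 2171 with the set as a block (1035 higher, 1136 lower). Of the genes higher in SH2 cells 290 passed in both conditions, against 16.2 for independent lists, and of the lower ones 490 against 38, with 0 in opposite directions. RPS12 (-2.85 ± 0.39, adjusted p = 0.000348), EXOSC5 (-1.81 ± 0.30; 0.00165), RAB1B (-1.32 ± 0.26; 0.0048) and KARS (-1.12 ± 0.24; 0.00793) were lower in treated SH2 cells. IGKC had 6583 counts in control against 2 in SH2 cells (ratio 6324, 1750 to 52230). CR2 was at least 887-fold lower, ACTL8 at least 568-fold, HLA-DRB5 at least 334-fold, EBI3 at least 254-fold and NLRP4 at least 249-fold. ITM2A (814 against 1 count), NAPSB (609 against 1) and MAL (1208 against 1) were lower too. ITM2A went from -9.92 to -6.20 without the treated control library of set 2, where it still passed, and missed the threshold in sets 2 and 4 alone (0.0598, and 0.0697 without doxycycline), as did MAL (0.0709). MAL, a T-cell protein, was also lost without the treated control library of set 2 (-4.53, adjusted p = 0.186). Higher in SH2 cells were IGLC7 (at least 432-fold), the adhesion molecule ICAM3 (at least 191-fold), FRMD3 (at least 132.5-fold), and IGLC6 (at least 106-fold). So were the collagen gene COL18A1 (at least 98.7-fold), TNFRSF18 (at least 83.8-fold), MGST2 (at least 83.6-fold), CRISP3 (at least 80.5-fold), TRPM4 (at least 77.4-fold) and IGLC3 (4352 against 2 counts). IGF2BP1 remained higher (4.42 ± 0.80, adjusted p = 0.00278) and HOXB4 lower (141 counts in control against 1 in SH2 cells; ratio 271, 47.8 to 10780). MHC class II genes (4 of 5 lower, also adjusted over the list alone; median -2.60, adjusted p = 1.01e-05, adjusted p = 0.455 with an estimated correlation) and MYC targets (7 of 29 lower, 8 adjusted over the list alone; median -0.51, adjusted p = 0.000971, adjusted p = 0.684 with an estimated correlation) were lower in treated SH2 cells. NF-kB targets (4 of 13 lower, also adjusted over the list alone; median -0.72, adjusted p = 0.00248, adjusted p = 0.455 with an estimated correlation), nuclear oxidative phosphorylation genes (5 of 44 lower, also adjusted over the list alone; -0.29; 0.0148, adjusted p = 0.884 with an estimated correlation) and glycolysis genes (2 of 21 lower and 1 higher, also adjusted over the list alone; -0.63; 0.0271, adjusted p = 0.884 with an estimated correlation) were called lower too. Oxidative phosphorylation lost the call without the treated control library of set 2 (0.0633) or the treated SH2 library of set 3 (0.0807), and glycolysis without treated control set 2 (0.381) or treated SH2 set 4 (0.0521). With the set as a block 8 lists were called in place of 5. In a fit on the compared groups alone 789 genes passed, and without the treated control library of set 2 or 4 there were 737 or 645.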

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

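The tests of the doxycycline effect in control cells, of the RPS12 copies, of the light chains, of the leak, of the block, and of the splits for the MYC list were chosen only after the results were seen; the set 4 tests and the splits for counts of genes and lists were set before.

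Single libraries stood far from the rest of their group in 19 of 145 groups of 4 values. In 10 of them, 1 or 2 counts stood against 0 in the other libraries, where the measure of distance is fixed at its maximum and the chance rate of 1 in 20 does not apply. The other 9 came from 122 groups with at least a pair of values other than 0, where chance gives about 6.1. The 10 were HOXB4 (0.337 CPM, treated set 4), ITM2A (0.419, treated set 1), CCL22 (0.302, untreated set 4, and 0.38, treated set 2), FAM129A (0.38, treated set 2), ACTL8 (0.82, untreated set 1), HLA-DRB5 (0.593, untreated set 2), MAL (0.33, treated set 3) and NAPSB (0.604, untreated set 4, and 0.33, treated set 3). IGKC stood at 1.81 CPM in untreated set 4 against at most 0.297 in the others, and COL18A1 at 54.1 CPM in untreated set 3 against 49.6 to 50.1. In the treated library of set 4, TAS1R1 was at 3.03 CPM against 43.5 to 45.6 and DTX3 at 4.38 against at most 0.38. The log2 difference of set 4 stood apart for the medians of B lineage genes (-1.28), adhesion and homing genes (-0.802), HOX and stem cell regulators (-0.603), drug efflux transporters (-0.402) and genes of the G1/S transition (0.501). In the interaction of doxycycline and cell type, camera at its preset correlation called MYC targets (median -0.334), interferon genes (1.05) and cholesterol synthesis genes (0.358). None of the 3 passed with an estimated correlation (adjusted p = 0.456, 0.961 and 0.796) or with fry (0.985 each), so a difference in response is not established for them. Neither of these tests was run with the set as a block.

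RPS12 was lower with doxycycline in SH2 cells, as were the reads counted for its pseudogene copy, which may be stray RPS12 reads. Counted reads moving from RPS12 to its copies are argued against. RPS12 summed with 16 copies still fell in every set, with a smallest log2 change of -2.26. The copies held at most 0.278% of this sum in any library, so it follows RPS12 itself. Reads whose alignment was not unique are outside these counts, so a move into that class was not tested. Of the 35 splits of the 8 SH2 libraries into 4 and 4, 2 gave as many genes as the real one, so chance is not excluded by that count; the other split called 267 genes, put sets 1 and 2 against 3 and 4, and points to a structure between sets, while among the 8 splits that part every pair the highest other count was 0. Doxycycline acting without the shRNA stays open: the interaction was -2.91, more than 2 standard errors below 0, but the control cells may be another clone or line and so may respond otherwise. Also open is an action of the shRNA on RPS12 other than through IGF2BP1, taken up under the other observations, or an effect of IGF2BP1 loss itself. Treated SH2 cells were also sorted for the reporter per the labels. The reporter and this sort cannot be told apart from the shRNA by the design.

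SH2 and control libraries differed before doxycycline. A difference between sets is argued against by the block, under which 914 of the 938 genes were still called. Cells of another clone or line may underlie the difference: in 12 of 12 libraries the major light chain was lambda for SH2 and kappa for control cells, and a B-cell clone usually keeps 1 light chain. The labels call all of them 697 cells, and which libraries hold which clone was not tested. A knockdown that leaks without doxycycline stays open: IGF2BP1 was higher in SH2 cells by 5.52 on the log2 scale, but control cells of another clone with 3 counts in all give no level to compare with.

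MYC targets were lower and interferon genes higher with doxycycline in SH2 cells. For MYC targets, the treated library of set 4 as the only source is argued against by sets 1 to 3, where the median closest to 0 was -0.227. Doxycycline alone stays open for them, since the interaction did not pass with an estimated correlation (adjusted p = 0.456) and the medians within set 2 were -0.301 in SH2 and -0.303 in control cells. Of the 35 splits 1, the real one, gave as small an adjusted p for MYC targets (3.52e-10, with 2.91e-06 as the smallest other), but the 8 splits that part every pair are too few for a share under 0.05; for the count of lists, 18 of 35 gave as many as the real 9, with 14 as the highest other, so chance is not excluded. For interferon genes, set 4 alone cannot be told apart from an effect of the shRNA, since the lowest median in sets 1 to 3 was -0.077 and the other medians 0.115 and 0.274, while doxycycline alone stays open too, with a control median of -0.178 and an interaction that did not pass with an estimated correlation. For both lists the reporter and the sort of treated SH2 cells for it cannot be told apart from the shRNA either.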

How the results depend on the processing

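Leaving out both SH2 libraries of set 4, restricting SH2 against control cells to sets 2 and 4, the recovered reads, the leave-one-out runs of gene lists and of the response correlation, and every run of the sequence word were added after seeing the data; the rest was planned. Over all pairs of a single gene or list and an alternative, 1711 kept direction and side of the threshold, 112 lost and 25 gained the call, and 25 turned direction; the cause was not tested except where fewer samples or genes explain it by construction. In treated against untreated SH2 cells the count of 2 genes became 47 without a filter, 6 with the set as a replicate block, 16 with DESeq2, 0 on the compared groups alone, 0 in sets 2 and 4, 1 without set 4 and 0 to 3 without single libraries. In control cells 3 passed without a filter and 0 without any single library. The interaction gave 3 without a filter, 1 with the block, 2 with DESeq2 and 0 without any single library. SH2 against control cells without doxycycline gave 1449 without a filter, 1505 with the block, 413 in sets 2 and 4 and 343 to 853 without single libraries; with doxycycline 2171 with the block, 789 on the compared groups alone, 652 in sets 2 and 4 and 645 to 1462. Without single libraries IGF2BP1 ranged from -1.32 to -0.73, HOXB4 from -4.42 to -2.50, MYB from -0.76 to -0.09 and ALDH1A1 from -1.35 to -0.09 in treated against untreated SH2 cells, all lower and none past the threshold. Lists called were 0 with an estimated correlation in all 5 contrasts and 0 with fry in the first 3, against 4 with fry for SH2 against control cells without doxycycline and 7 with it, where the block gave 8. Without single libraries the counts of lists were 5 to 12 (treated SH2), 4 to 7 (treated control), 3 to 10 (interaction), 7 to 12 and 4 to 9 (SH2 against control, without and with doxycycline). The response correlation was 0.252 over genes with a mean log2 CPM of at least 5, 0.089 without SH2 set 4 and 0.009 to 0.193 without single libraries. None of the genes that turned direction had passed the threshold. IGF2BP3 became 0.03 in treated SH2 cells without set 4, and in the interaction 0.03 with the block, 0.27 without set 4 and -0.28 to 0.20 without single libraries. Without doxycycline MYB became -0.14 and ALDH1A1 -0.12 with the block, and without single libraries they ranged from -0.24 to 0.41 and from -0.23 to 0.69. In control cells the ranges without single libraries were -0.99 to 4.09 for IGF2BP1, -0.50 to 1.11 for HOXB4, -0.20 to 0.13 for MYB, -0.09 to 0.37 for ALDH1A1 and -0.44 to 0.03 for IGF2BP3. The unfolded protein response list had adjusted p-values of 2.12e-05 to 0.848 there and turned direction without untreated control set 4 (0.569). MX1 became -0.21 without SH2 set 4 and ranged from -0.22 to 2.65 without single libraries, the lowest without the treated library of set 4. Beyond those named here and in the report, the block changed the call of no named gene and of no list called. Depth limits the low genes: HOXB4 rested on 12 counts in SH2 cells.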

Other observations

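The search for words was thought of after the fall of RPS12 was seen, and its prediction was written before it was run; the tests of both directions, of the word's 8-base form, of sets, of sequence outside untranslated regions, of MYC targets and of splits were chosen only after its result was seen.

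Genes of the G2 and M phases of the cell cycle leaned upward with doxycycline in both cell types without passing: 23 of 26 were positive in SH2 cells (median 0.34; camera adjusted p = 0.139) and 22 of 26 in control cells (0.27; adjusted p = 0.102), and 0 members passed adjusted over the list alone in either. Replication-dependent histone genes, which lack the poly(A) tail that the library kit captures, were not called. Their fitted values were negative for 9 of 9 members in SH2 cells (median -0.26, camera adjusted p = 0.115) and 8 of 9 in control cells (-0.25, camera adjusted p = 0.0899). Sets differed, with set 4 lowest in both cell types. The medians were 0.135, -0.294, -0.035 and -0.983 in SH2 sets 1 to 4, and -0.145 and -0.942 in control sets 2 and 4. Cytosolic ribosomal protein genes had a median of -0.045 over 75 members in SH2 cells, with RPS12 as the 1 that was lower (adjusted p = 0.256 for the list). Reported targets of IGF2BP1 had a median of 0.037 over 18 members (adjusted p = 0.886), with 10 positive.

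A seed match of the shRNA, as small RNAs make in untranslated regions, is a hypothesis for the fall of RPS12. The shRNA sequence is not given in the sources used here, so words of 7 bases from the IGF2BP1 transcript were compared over the 3' UTR of 10614 genes, adjusting for length and base composition. Of 5694 words 2 passed the Bonferroni correction for lower genes, GCAAGGA (z = -9.76) and the overlapping CAAGGAA (z = -7.09), while the lowest of 10606 other words had -4.31. With both directions corrected over all 16300 words, 4 words passed for higher genes, also from the IGF2BP1 transcript: CTTTGGG (5.58), GCACTTT (5.05), TGCACTC (4.81) and CACTTTG (4.71). Of these, GCACTTT, CACTTTG and CTTTGGG overlap each other, so they are not independent. The z of words is therefore not quiet apart from the lower pair. Genes with GCAAGGA in the 3' UTR (1465) differed from the others by -0.134 ± 0.015 (SE) on the log2 scale with doxycycline in SH2 cells, and by -0.114, -0.101, -0.101 and -0.163 in SH2 sets 1 to 4. In control cells the difference was -0.011 ± 0.016, with 0.0 ± 0.014 in set 2 and -0.03 ± 0.017 in set 4. The word had z = -2.14 there, and the lowest z of an IGF2BP1 word was -3.84. The difference between the cell types itself was not tested. Under the settings listed for this comparison the value ran from -0.152 to -0.118. The longer form GCAAGGAA, picked among several extensions looked at, went with -0.169 ± 0.023 over 519 genes. Since z and these SEs treat genes as independent, the 35 splits of the SH2 libraries were searched too: 1 of them, the real one, gave a word with as large a z. In the other splits the largest z, without regard to sign, ran from 3.98 to 8.82. Most of them thus held a word past the correction too, so passing it says little alone. For GCAAGGA itself the highest other was 7.49. The highest other, 8.82, came from 1 of the 8 splits that part every pair, which are too few for a share under 0.05.

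The word occurs in IGF2BP1 at 49038401 to 49038407 (exon 6) and 49041437 to 49041443 (exon 8) in the coding sequence and at 49052026 to 49052032 (exon 15) in the 3' UTR of chromosome 17. RPS12 carries it in the coding sequence of exon 6, at 132817487 to 132817493 of chromosome 6, in GTTAAGGACTATGGCAAGGAG, and RP11-864N7.2 at 74745765 to 74745771 of chromosome 11. RAB1B and EXOSC5 carry it in the 3' UTR and KARS does not. Of the title genes besides IGF2BP1, HOXB4 carries it in the 5' UTR, while MYB and ALDH1A1 lack it. The word is common: of 10614 genes searched, 1465 had it in the 3' UTR and a further 1718 only outside it. Its presence in a named gene therefore says little alone. Outside the 3' UTR, where RPS12 carries it, the word went with -0.064 ± 0.013 in SH2 cells, and with -0.036 ± 0.013, -0.041 ± 0.013, -0.019 ± 0.014 and -0.106 ± 0.025 in sets 1 to 4. In control cells this was 0.0 ± 0.014, with 0.038 ± 0.012 in set 2 and -0.025 ± 0.016 in set 4. Cleavage through a long unbroken shared stretch is argued against, since the RPS12 and IGF2BP1 transcripts searched share at most 10 bases in a row. As long a stretch was found for 200 of 200 genes of similar length. Pairing with mismatches was not searched. The values for the 3' UTR are in line with a seed match but may also come from a feature that goes with the word, and whether it bears on RPS12, whose word lies in coding sequence, stays open. For MYC targets, the word in their own transcripts does not account for the shift: 21 members without it had a median of -0.386, with 19 of them lower. An effect on MYC targets through other genes that carry the word was not tested.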
